A study of Homo sapiens with 6 samples.

How the data were processed

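Total RNA of PC3 cells was measured 72 h after transfection with 10 nM of control or GGCT siRNA, in 3 independent experiments, with 1 array per group and experiment. Per the labels, RNA was extracted with Trizol, purified on RNeasy columns, and turned into Cy3-labelled cRNA with the Low Input Quick Amp kit. Per the file headers, the spot intensities (processed signal) were made with Agilent Feature Extraction 12.1.0.3 (protocol GE1_1200_Jun14, array design 072363, annotated on hg19), which subtracted the background, removed spatial trends and replaced low values by a positive surrogate; they were not scaled between arrays. The median spot and local background intensities in the same files were as deposited, raw pixel medians per the file headers. The authors' value table held log2 values, which by comparison with the scanner files had been scaled to each array's 75th percentile and then reduced by each probe's median over the 3 control arrays; the scaling is not stated by the authors. Of its 58329 probes, 58191 were matched, the lowest correlation with values made the same way was 0.9996 and the largest SD of the difference was 0.0207. Its column medians were 0, 0 and 0 for the control arrays and 0.0246, 0.0444 and 0.0758 for the GGCT siRNA arrays.

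Each array had 62976 spots, 60900 of them not controls, for 58200 probes; 1 malformed line on GGCT siRNA array 1 was left out with its probe. Per array, 46 to 129 non-control spots carried an outlier flag and were left out, and no spot was saturated. Spots of a probe were averaged. Values were log2 of the processed signal minus the array's 75th percentile over non-control probes. The files held neither gene names nor mean signals, so symbols were taken from the RefSeq accession of each probe without its version, through a table of names on a later genome release (names only, no coordinates compared), and the alternative that asked for mean signal used the median signal. A symbol was found for 34891 probes and not for 23309, whose units carry an accession only. Probes with a missing value (16) were left out. A probe was kept when well above background on all 3 arrays of at least 1 group, which left 31059, and the brightest probe stood for a gene. This gave 24859 genes, 17064 with a symbol and 7795 named by accession only; 4897 had 2 or more kept probes. The share of probes well above background was 53.5 to 54.5% per array.

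The groups were compared with limma 3.58.1 (lmFit and eBayes without trend, two-sided) in R 4.3.3 with the package data.table (version 1.17.8), without a block, and p values were adjusted by Benjamini-Hochberg over the genes at a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A gene well above background on no array of 1 group and on all arrays of the other is reported as a bound against the background limit. The limit was the lowest signal of any probe called well above background on an array, or the gene's own signal where that was higher. Gene lists, the test, the filters, the alternatives planned and the rule for named genes were fixed before the data were examined. The rule took GGCT, the 10 largest rises and 10 largest falls that passed, did not overlap between groups and were well above background on all 6 arrays and had a symbol, the 3 largest bounds each way, up to 4 passing members per list by size of change, and CDKN1A, CDKN2A, FOXO3, PRKAA1, PRKAA2, MYC and PHB2. The 34 lists were the gamma-glutamyl cycle and glutathione metabolism, CDK inhibitors and senescence markers, FOXO targets, AMPK and energy stress, DNA replication, G2/M and mitosis, DNA repair, p53 targets, NRF2 targets, ATF4 and amino acid stress, unfolded protein response, heat shock, cholesterol synthesis, fatty acid synthesis, interferon response, NF-kB and secreted inflammatory factors, epithelial and mesenchymal genes, TGF-beta targets, glycolysis, hypoxia, oxidative phosphorylation, ribosome biogenesis and MYC targets, lysosome and autophagy, apoptosis regulators, iron handling, metallothioneins, prohibitins, receptor kinase feedback, luminal prostate, neuroendocrine, leukocyte, endothelial and stromal markers, and RNA interference machinery. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over 33 lists, and again with an estimated correlation and with fry.

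The experiment numbers were checked as pairs. Deviations from the group means correlated, across genes, at 0.58, 0.46 and 0.29 between arrays of the same number and at -0.476 to 0.116 between arrays of different numbers. The design also states independent experiments, so the numbers were taken to pair the arrays. Experiment 1 was alone on its slide, so that its 0.58 cannot be told apart from a slide effect. Through the centring on group means, such an effect can also raise the 0.46 and 0.29. That centring also lowers the correlations between different numbers by construction. The pairing is used as a block among the alternatives and not in the main fit. Slides were read from the files. On simulated data of the same size (10 simulations, 200 changed genes per size), the test recovered 14.0% of changes of 0.5, 79.7% of changes of 1 and 97.8% of changes of 2 on the log2 scale, with 5.15% false calls. The changed list was called in all 10 simulations, with 2 calls of other lists. Simulated genes varied independently, without an experiment or slide effect, and far fewer changed than were called on the arrays. The recovered shares thus do not carry over to the real comparison, and the list calls do not bear on lists of correlated genes.

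The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median scaling, no filter on dim probes, a filter requiring all 6 arrays, the mean of a gene's probes, each probe on its own, an intensity trend with robust prior, the experiment number or slide as a block, the authors' value table, an unmoderated test, and leaving out each array. The second slide alone, slide as a random block, and the experiment block with an estimated correlation were chosen after seeing the data. A search for seed matches of the siRNAs was not run, since no transcript sequences were at hand.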

Results

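The series measured gene expression in PC3 cells, an established human prostate cancer line that lacks functional p53, with 6 one-colour microarrays. Cells of 3 independent experiments received 10 nM of either a non-targeting control siRNA or an siRNA against GGCT, the gene for gamma-glutamylcyclotransferase, an enzyme of glutathione breakdown. RNA was taken after 72 h, which gave 3 arrays per group. The 75th percentile of the processed signal was 317.0, 304.3 and 324.7 on the control arrays and 315.6, 301.3 and 319.7 on the GGCT siRNA arrays, and between 31114 and 31725 of the 58200 probes lay well above background on an array. No spot was saturated. The number of arrays limits the precision of every value below. The comparison of the groups asks how depleting GGCT alters gene expression in these cells. Changes are log2 fold changes of GGCT siRNA against control siRNA, positive where expression was higher after GGCT siRNA, and levels are log2 signal relative to each array's 75th percentile.

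GGCT itself, on chromosome 7, fell 21.3-fold. Its level was 5.44, 5.31 and 5.30 on the control arrays (mean 5.35 ± 0.077, SD, n = 3) and 0.93, 0.945 and 0.948 on the GGCT siRNA arrays (mean 0.941 ± 0.0094, SD, n = 3). The log2 change was -4.41 (SE 0.084, limma adjusted p = 2.35e-05), so that 4.7% of the control level was left (95% interval 4.08 to 5.42%). A second, dimmer probe for another transcript record of GGCT changed by -2.06, which left 23.9% (95% interval 17.4 to 32.8%).

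Depletion of GGCT was accompanied by changes in 11819 of the 24859 genes tested (47.5%), of which 5771 were higher and 6048 lower at an adjusted p under 0.05. The balance depended on the scaling, with 5211 higher and 6604 lower under median scaling and 5888 higher and 6032 lower under quantile normalization. At least 2-fold changes were seen in 2176 of the higher and 2166 of the lower genes. The groups did not overlap in 14262 genes (57.4%), against 10% by chance. The arrays correlated at 0.99 to 0.996 within groups and at 0.949 to 0.962 between groups, across genes, which are not independent replicates. Experiment 1 of both groups was on 1 slide and experiments 2 and 3 were on another. With slide as a block, 6952 genes were higher and 7199 lower, and within the second slide alone 5635 were higher and 5985 lower. The other slide held 1 array per group and gives no test of its own. A limma interaction of slide and siRNA passed in 0 genes at an adjusted p under 0.05 and in 1424 at an unadjusted p under 0.05, with 2 residual degrees of freedom.

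The largest rises among genes with a symbol and well above background on all 6 arrays were those of IL13RA2, a decoy receptor for interleukin 13, at 6.78 (SE 0.34, adjusted p = 5.09e-05), and SPINK1, a secreted trypsin inhibitor, at 6.09 (SE 0.15, adjusted p = 2.35e-05). LAMP5 rose by 5.53, the integrin subunit gene ITGB3 by 5.40, the neutral sphingomyelinase gene SMPD3 by 5.23 and the secreted metalloproteinase gene ADAMTS6 by 5.21 (3.30 at its other probe). CPA4, a carboxypeptidase, DHRS9, a dehydrogenase, PDE2A, a phosphodiesterase, and ADAMTS14 rose by 4.97, 4.64, 4.47 and 4.45. Among the same genes the largest fall was that of SHCBP1, at -4.64 (SE 0.16, adjusted p = 2.67e-05), followed by GGCT and by MAP2K6, a kinase that activates p38, at -4.30. LIMCH1 changed by -4.01 (-2.82 at its other probe), the condensin subunit gene NCAPG by -3.92 and NDUFA5, a subunit of respiratory complex I, by -3.92. MSMP, PEX19, DNAJC15 and MAL2 changed by -3.92, -3.91, -3.88 and -3.74, the last by -1.71 at its other probe; PEX19 serves protein import into peroxisomes. Groups without overlap were a condition for choosing these 20 genes, so that their lack of overlap is no further result. The order of rises and of falls changed with normexp, where SHCBP1, at -3.37, lay behind GGCT and behind MSMP, at -3.89, NDUFA5, at -3.69, MAL2, at -3.65, and PEX19, at -3.43.

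**Figure D1:**
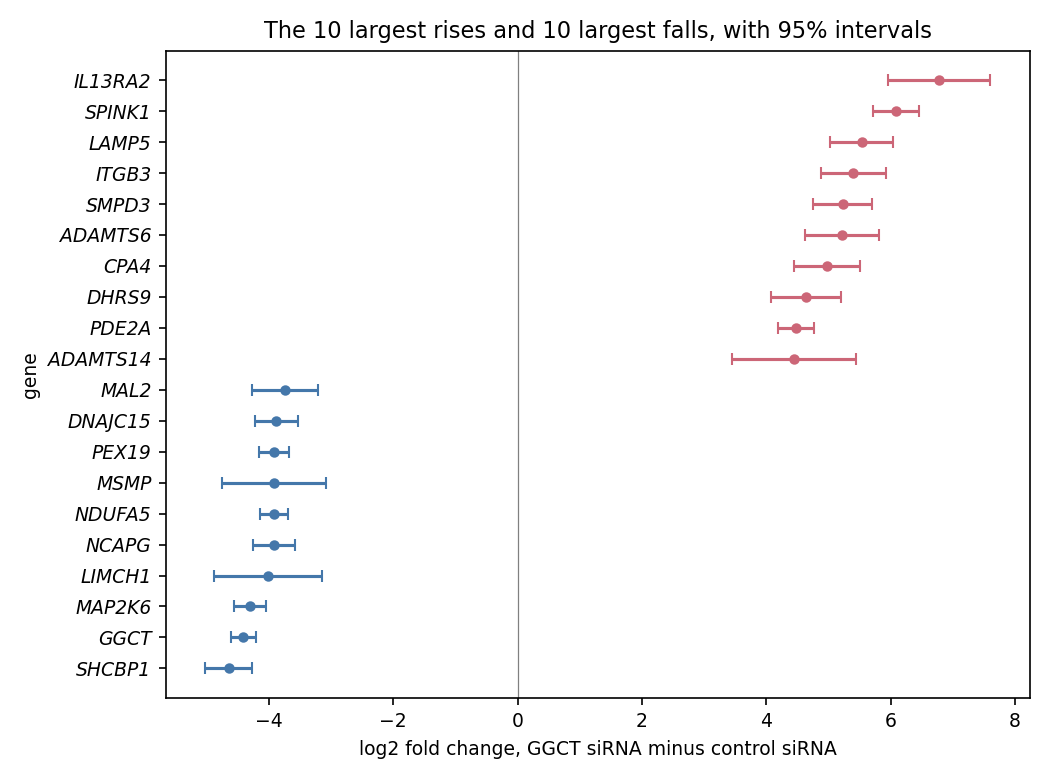
Log2 fold change (GGCT siRNA against control siRNA) of the 10 genes with the largest rise and the 10 with the largest fall among passing genes with a symbol and well above background on all 6 arrays, with the 95% intervals of the limma fit as error bars, rises in red and falls in blue. The rises run from 4.45 to 6.78 and the falls from -3.74 to -4.64.

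Some genes were well above background in 1 group only, so that their fold is given as a bound, computed against the background limit of the other group. That limit is set per array and is not a detection limit of the gene's own probe, so that "at least" holds only for the limit used. Of the genes with a bound, 329 had a higher level after GGCT siRNA, 319 of them past the threshold, and 258 a lower level, 243 of them past it. SUN3 was at least 90.4-fold higher, TIE1, an endothelial receptor kinase, at least 31.1-fold and the chemokine gene CCL20 at least 27.6-fold. COL21A1, a collagen gene, was at least 15-fold lower, SCIN at least 8.03-fold and KCNV1 at least 6.36-fold. For SUN3 and KCNV1 the bounds nearly equal the fitted folds of 91.3 and 6.4, so that they add no safety margin. These bounds hold for the processed signal: with normexp, whose offset of 50 shrinks ratios of dim spots, the fitted log2 changes were 3.21, 1.95 and 2.05 for SUN3, TIE1 and CCL20 and -1.32, -0.85 and -0.66 for COL21A1, SCIN and KCNV1, all smaller than the bounds and past the threshold.

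Genes of AMPK, FOXO3a, p21 and related regulators were fixed as a set of 7 to be reported in any case. CDKN1A, which encodes the cell cycle inhibitor p21, rose 7.54-fold (log2 2.92, SE 0.11, adjusted p = 3.21e-05). FOXO3, the transcription factor gene, rose 2.4-fold (log2 1.26, adjusted p = 0.000346), with its 3 probes between 1.07 and 1.29. The AMPK catalytic subunit genes fell, PRKAA2 by 2.96 (adjusted p = 3.38e-05) and PRKAA1 by 0.62 (adjusted p = 0.00126) on the log2 scale. CDKN2A, a second cell cycle inhibitor gene, changed by -1.35 (adjusted p = 0.000587), and MYC by 0.42 (adjusted p = 0.0123). PHB2, a prohibitin gene, did not pass the test (0.05, adjusted p = 0.683). The arrays measured RNA and not the activity or phosphorylation of these proteins. With a normexp background correction and an offset of 50, CDKN1A changed by 1.69 and PRKAA2 by -1.58, still past the threshold.

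**Figure D2:**
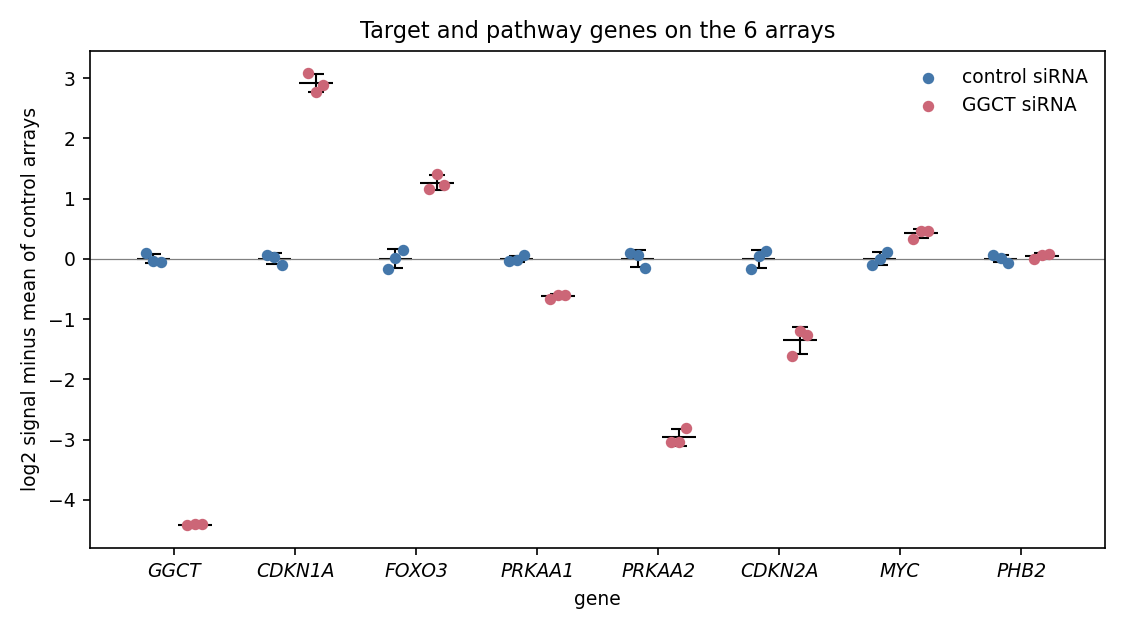
Log2 signal (relative to each array's 75th percentile) minus the mean of the control arrays, for GGCT and the 7 fixed genes; points are the 3 control siRNA and 3 GGCT siRNA arrays, horizontal lines are group means and error bars are SD. CDKN1A, FOXO3 and MYC lay higher and GGCT, PRKAA1, PRKAA2 and CDKN2A lower after GGCT siRNA, while PHB2 did not pass the test.

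Genes of cell division fell as a group. Of the 66 measured genes of the G2/M and mitosis list, 62 were lower, 1 was higher (BUB3) and 3 did not pass, with a median of -1.53 and a quartile range of -1.88 to -0.987. CKAP2, CKAP2L and CDCA3, which act on the spindle or in mitotic entry, changed by -3.10 (-1.92 at the other CKAP2 probe), -2.95 and -2.78. The list fell relative to other genes (camera adjusted p = 4.7e-19; adjusted p = 0.496 with an estimated correlation). Of 49 genes of DNA replication and G1/S, 39 were lower, 3 higher (CCNE1, GINS3 and UHRF1) and 7 did not pass. RRM2, a subunit of ribonucleotide reductase, changed by -3.59, the transcription factor gene E2F2 by -2.14 and GINS2, part of the replicative helicase, by -2.07 (list median -0.933, adjusted p = 7.13e-11; adjusted p = 0.472 with an estimated correlation). Of 30 DNA repair and Fanconi genes, 23 were lower, 1 higher (PALB2) and 6 did not pass, among the lower BARD1 at -2.07, FANCI at -1.40 and FANCA at -1.36 (list median -0.735, adjusted p = 2.32e-06; adjusted p = 0.472 with an estimated correlation). The medians of the differences within experiments 1, 2 and 3 were -1.82, -1.32 and -1.40 for G2/M and mitosis and -1.02, -0.853 and -0.92 for DNA replication. The higher genes named with these lists, and those named as exceptions of the lists that follow, were chosen after their values were seen unless the rule for named genes also took them.

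The lists of glycolysis, heat shock, oxidative phosphorylation and ribosome biogenesis also fell relative to other genes, the last pair with many members that did not pass. All 22 measured genes of glycolysis passed, 20 lower and 2 higher (HK1 and SLC16A1), with PGAM1 at -2.06, the lactate dehydrogenase gene LDHA at -1.77 and PGK1 at -1.74 (list median -0.779, adjusted p = 2.55e-05; adjusted p = 0.502 with an estimated correlation). Of 23 heat shock genes, 17 were lower, 5 did not pass and DNAJB4 rose by 1.22 (0.75 with normexp). BAG3, a co-chaperone, changed by -1.59 and the chaperone genes HSPA8 and HSPH1 by -0.87 and -0.85 (list median -0.597, adjusted p = 0.000217; adjusted p = 0.322 with an estimated correlation). Of 50 oxidative phosphorylation genes, 20 were lower, 29 did not pass and UQCRC1 was higher; NDUFB5 changed by -1.53 and ATP5MC1 by -1.03 (list median -0.251, adjusted p = 0.000218; adjusted p = 0.571 with an estimated correlation). Of 44 genes of ribosome biogenesis and MYC targets, 21 were lower, 21 did not pass and 2 were higher (MYC and ODC1), with PA2G4 at -1.48 and NHP2 at -0.75 (list median -0.259, adjusted p = 0.00313; adjusted p = 0.571 with an estimated correlation).

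The lists of inflammatory factors, of lysosome and autophagy, and of mesenchymal genes rose relative to other genes, each with members that fell. Of 39 genes of the NF-kB and secreted inflammatory factors list, 25 were higher, 11 did not pass and 3 were lower (IGFBP5 at -3.53, IL33 at -2.93 and AREG at -1.96). MMP3, a matrix metalloproteinase, rose by 4.39 and SERPINB2, a protease inhibitor well above background on 2 of the 3 control arrays, by 4.27 (2.03 with normexp). CCL20 is given above as a bound, and CSF3, a growth factor for granulocytes, was at least 11.9-fold higher (a log2 change of 1.30 with normexp). The list median was 1.35, or 1.32 with the 3 genes below background in 1 group at their bounds (adjusted p = 9.87e-05; adjusted p = 0.496 with an estimated correlation), and it was 1.16, 1.54 and 1.28 within experiments 1, 2 and 3. Of 46 lysosome and autophagy genes, 25 were higher, 4 lower (ATG12, ATP6V1A and NBR1 among them) and 17 did not pass. The autophagy kinase gene ULK1 rose by 1.95, the sialidase gene NEU1 by 1.56, the cathepsin gene CTSB by 1.41 and NPC2 by 1.36 (list median 0.359, adjusted p = 0.000149; adjusted p = 0.238 with an estimated correlation). Of 25 mesenchymal genes, 13 were higher, 5 lower (FN1, LOX, LOXL2, SPARC and VIM) and 7 did not pass; the collagen gene COL5A1 rose by 3.15 and the matrix protein gene SPARC changed by -3.64 (list median 0.518, adjusted p = 0.00691; adjusted p = 0.496 with an estimated correlation). Markers of stromal cells share members with this list, COL1A1 at 1.94 and ACTA2 at 1.45 (0.70 with normexp).

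The lists of TGF-beta and FOXO targets rose relative to other genes. Of 28 TGF-beta target genes, 17 were higher, 6 lower and 5 did not pass, with BAMBI, a TGF-beta pseudoreceptor, at 2.21 (list median 1.04, adjusted p = 0.0292; adjusted p = 0.689 with an estimated correlation). That call was lost without control array 3 (adjusted p = 0.0506) and without GGCT siRNA array 1 (adjusted p = 0.0822), with a range of 0.00277 to 0.0822 over 18 alternatives. Of 32 FOXO target genes, 16 were higher, 8 lower and 8 did not pass. KLF2, a transcription factor gene, rose by 2.97, CDKN1A by 2.92 and IRS2, an insulin receptor substrate, by 1.91, while BNIP3, a mitophagy gene, changed by -2.10 (list median 0.515, adjusted p = 0.0424; adjusted p = 0.496 with an estimated correlation). The FOXO call was lost with the experiment number as a block (adjusted p = 0.0825), with slide as a block (adjusted p = 0.0819), within the second slide (adjusted p = 0.0633) and without control array 2 (adjusted p = 0.0917), GGCT siRNA array 1 (adjusted p = 0.0915) or GGCT siRNA array 3 (adjusted p = 0.0548); the range over 18 alternatives was 0.0123 to 0.0917.

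**Figure D3:**
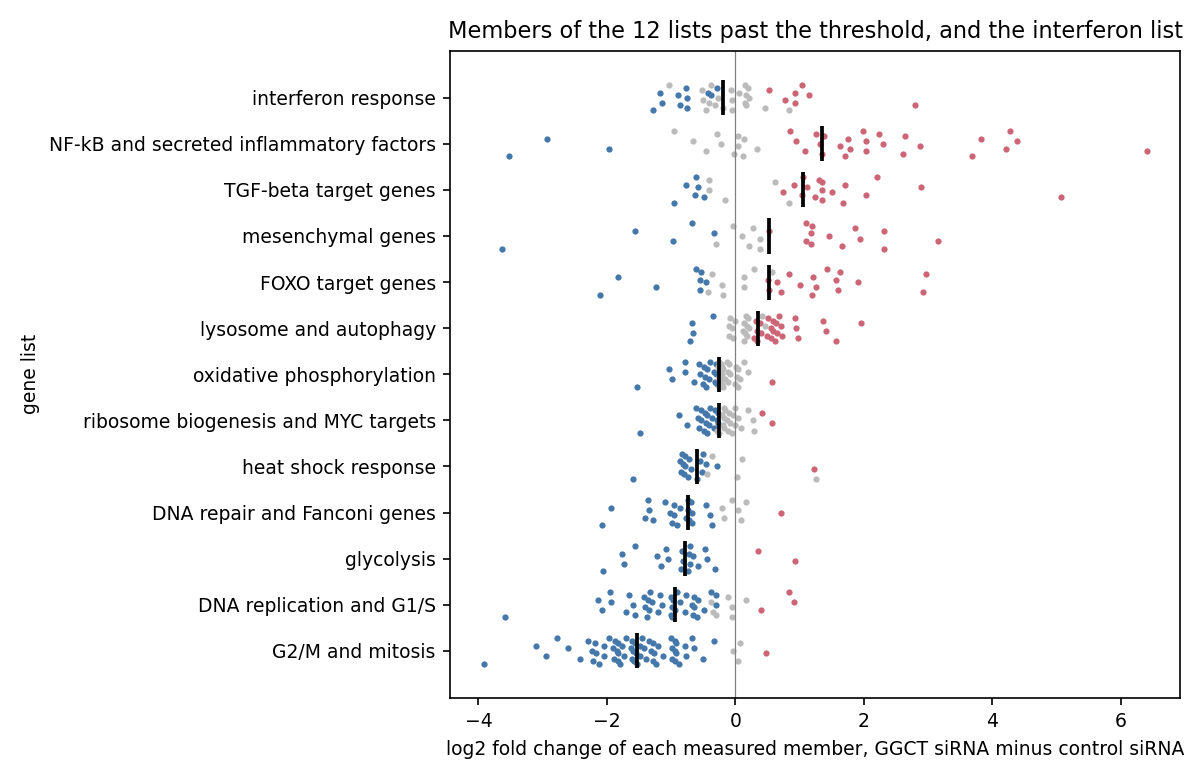
Log2 fold change of each measured member of the 12 lists that passed and of the interferon list; red and blue points passed an adjusted p under 0.05 as higher and lower, grey points did not, and black bars are medians. The G2/M and mitosis median lies at -1.53 and the NF-kB median at 1.35; genes below background on the control arrays, such as CCL20 and CSF3, are drawn at their fitted values and not at their bounds.

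The lists nearest to the study's target and to p21 did not pass as lists. In the gamma-glutamyl cycle and glutathione list, 10 of 33 genes were lower, 3 higher (GCLC, GGT5 and GPX4) and 20 did not pass (median -0.28, adjusted p = 0.0993); the list passed, downward, without a filter on dim probes (adjusted p = 0.00804) and with each probe tested (adjusted p = 0.042), over a range of 0.00804 to 0.155 in 18 alternatives. GGCT itself, the target of the siRNA, is among the 10 lower genes and was kept in every test of this list. Its imposed fall thus adds to the downward calls, and the list was not tested without it. Besides GGCT, the cystine transporter gene SLC7A11 changed by -2.88 and the oxoprolinase gene OPLAH by -1.33. Of 18 CDK inhibitors and senescence markers, 5 were higher (among them CDKN1A, FUCA1, GLB1 and TNFRSF10D, the last at least 1.55-fold, or 0.18 on the log2 scale with normexp), 6 lower and 7 did not pass; the median was -0.0761 and the mean 0.242 (adjusted p = 0.873). In the AMPK and energy stress list, 8 of 29 genes were higher, 8 lower and 13 did not pass, with a median of -0.0308 and a mean of 0.0895 (adjusted p = 0.873); the sestrin gene SESN2 rose by 2.19 and TBC1D1 by 1.65 (0.461 at its other probe). Of 28 p53 target genes, 13 were higher, 7 lower and 8 did not pass (median 0.183, adjusted p = 0.161), with ZMAT3 at 1.90 (1.12 with normexp) and the death receptor gene FAS between 1.57 and 3.23 over its 4 probes. The interferon list had 7 higher, 11 lower and 21 not passed of 39 (adjusted p = 0.824), with SAMD9 at 1.15 (0.49 with normexp) and RSAD2 at -1.28 (-0.40 with normexp). The call of RSAD2 was lost in 7 of 20 alternatives, normexp among them.

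Most stress and metabolic lists that did not pass held genes that went both ways. In the NRF2 list, 10 of 30 genes were higher and 8 lower (adjusted p = 0.873), with ME1, the malic enzyme gene, at -3.15, the heme oxygenase gene HMOX1 at 2.98 and PIR at -2.12. The ATF4 and amino acid stress list had 12 higher and 14 lower of 38 (adjusted p = 0.873), with ALDH18A1 at -2.31 and the amino acid transporter gene SLC7A5 at 2.06. In the unfolded protein response list, 7 of 25 were higher and 4 lower (ATF6, DNAJB9, EDEM1 and SDF2L1; adjusted p = 0.437), with DNAJB9 at -1.77. Of 25 cholesterol synthesis genes, 8 were lower and none higher (adjusted p = 0.158), among them STARD4 at -1.24, HSD17B7 at -1.19 and ACAT2 at -1.19. That list passed, downward, without a filter on dim probes (adjusted p = 0.0294), without control array 1 (adjusted p = 0.0185) and within the second slide (adjusted p = 0.0122), over a range of 0.0122 to 0.392. The fatty acid synthesis list had 7 higher and 7 lower of 23 (adjusted p = 0.873), with DGAT2 at 1.60, ELOVL6 at 1.30, ME1 at -3.15 and SCD5 at -1.28 (-0.72 with normexp). In the hypoxia list, 6 of 25 were higher and 12 lower (adjusted p = 0.178), with STC1 at 2.10 and HIF1A at -1.57. The iron handling and ferroptosis list had 8 higher and 4 lower (CP, IREB2, SLC40A1 and SLC7A11) of 21 (adjusted p = 0.203), with AIFM2 at 1.13. Of 10 metallothionein genes, 5 were higher (MT1A, MT1B, MT1E, MT1L and MT1X, which rose by 1.93) and none lower (adjusted p = 0.0556); the list passed in 11 of 18 alternatives, over a range of 0.00682 to 0.122, with 0.047 for the experiment block, 0.036 for the slide block, 0.0199 within the second slide, 0.00682 without control array 1 and 0.0407 without GGCT siRNA array 3. The calls of MT1E and MT1L were lost without single arrays, MT1E without control array 3 and MT1L without control array 2, control array 3 or GGCT siRNA array 1 (largest adjusted p = 0.0568 and 0.0608), and with the unmoderated test, MT1E also with the mean of its probes (0.61) and MT1L without a filter on dim probes. The list of prohibitins and mitochondrial quality control had 2 higher (PINK1 and YME1L1) and 8 lower of 18 (adjusted p = 0.199), with the mitochondrial fusion genes MFN1 at -1.46 and OPA1 at -1.35 (-0.226 at its other probe).

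Signalling, apoptosis and RNA interference lists did not pass either. The list of receptor tyrosine kinases, MAPK and PI3K feedback had 17 higher and 7 lower of 36 (adjusted p = 0.178), with the phosphatase gene DUSP1 at 2.35 and SPRY1 at -2.55. Of 37 apoptosis regulators, 12 were higher and 9 lower; the median was -0.0229 and the mean 0.141 (adjusted p = 0.873, camera upward and fry downward). BMF, a BH3-only gene, rose by 2.97 and BIRC3 by 1.70. The RNA interference list had 4 higher (AGO1, AGO2, PRKRA and TNRC6C) and 3 lower (AGO3, DICER1 and TNRC6B) of 13 (adjusted p = 0.873), with DICER1 at -1.02; the call of TNRC6C was lost without GGCT siRNA array 2 or 3 (largest adjusted p = 0.0582) and with the unmoderated test.

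Lineage and cell type lists did not pass where tested. The epithelial list had 4 higher (CLDN1, JUP, KRT8 and TJP1) and 5 lower (CLDN3, ESRP2, ITGA6, KRT18 and KRT19) of 28 (adjusted p = 0.923), with TJP1 at 1.46 and CLDN3 at -1.51. Of 13 measured androgen receptor and luminal prostate markers, 4 were higher (PLPP1, PMEPA1 and SLC45A3 among them) and 4 lower (ACP3, FKBP5, HOXB13 and NDRG1; adjusted p = 0.873, camera downward and fry upward), with HOXB13 at -1.84 and PMEPA1 at 1.67. Of 6 measured leukocyte markers, CSF1R passed, at 3.68 (1.17 with normexp), and was well above background on 1 of the 3 control arrays (list adjusted p = 0.559). Endothelial and stromal markers had 4 higher (ACTA2, COL1A1, COL1A2 and PDGFRA) and TEK lower of 12 (adjusted p = 0.207). Only 3 neuroendocrine markers were measured, too few for a test: SYP was at least 2.83-fold higher (a log2 change of 0.31 with normexp), ENO2 changed by -1.16, and SCG2 passed at 1.15, a call lost with normexp (0.15), with the unmoderated test and within the second slide.

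In all, 12 of the 33 tested lists passed, 5 upward and 7 downward. With an estimated correlation 0 lists passed in camera (smallest adjusted p = 0.238), with 3 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, passed 22. Adjusted over the list alone, the counts of higher and lower members were the same as over all genes, except that DNA replication had 42 lower, lysosome 26 higher, heat shock 2 higher, oxidative phosphorylation 19 lower, ribosome biogenesis 22 lower, TGF-beta 8 lower, glutathione 2 higher and 8 lower, CDK inhibitors 6 higher, cholesterol 7 lower, the kinase list 8 lower, prohibitins 3 higher, unfolded protein response 6 higher, NRF2 10 lower, RNA interference 6 lower and epithelial 3 higher and 4 lower. A single siRNA sequence against GGCT was used, so that effects of that sequence on other genes and effects of losing GGCT are not separated by the comparison. Changes of dim genes depended on the background correction. With normexp, the log2 change of 42 of 144 named genes other than GGCT moved by over 1.5 times, and 37 of these still passed. Of the 20 genes plotted as largest rises and falls, those whose log2 change moved so far were LAMP5, to 3.47, ADAMTS14, to 2.51, LIMCH1, to -2.24, NCAPG, to -1.68, and DNAJC15, to -2.33. Genes near background moved further. On the fold scale more of the plotted genes moved by over 1.5 times, such as ADAMTS6, whose log2 change went from 5.21 to 3.50.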

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

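The second slide alone, slide as a random block, and the experiment block with an estimated list correlation were tests chosen after the result was seen. GGCT fell past the threshold under every alternative run, between -4.47 and -3.24. The number of changed genes was 10403 to 14212 over the alternatives that test one unit per gene on all arrays, 9765 to 11071 without single arrays (higher 4776 to 5482, lower 4982 to 5759), and 4342 when a change of at least 2-fold was also asked. The replicate block gave 14212 and kept 11656 of the 11819 calls; it and the slide block changed no list call other than FOXO targets, which was lost, and metallothioneins, which was gained. The count of lists was 10 to 14 without single arrays, 0 with an estimated correlation, 22 with fry, and 0 with the experiment block and an estimated correlation; it lay between 12 and 15 under the other alternatives. The estimated correlation counts shared movement of a list's genes within groups against the list, by construction, and fry does not compare a list with other genes. The unmoderated test and the random slide block gave no list value. Of the values for named genes, 2815 kept direction and side of the threshold, 44 no longer passed, and PHB2, which had not passed, was reversed with median scaling (-0.00888), by construction, since that scaling shifts every gene alike and moved the median of all genes from -0.00568 to -0.0618. The normexp offset shrinks ratios of dim spots by construction. Signal over background limits the folds of genes near background in 1 group. The alternatives for the seed search were not run.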

Other observations

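The tests of gene families, histones, scaling, experiments, interferon, leukocytes, splits and the siRNA were chosen after the result was seen; those of probes that moved apart were written before it.

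Clustered histone genes, which are expressed mainly with DNA replication, differed by type in how many were higher or lower. All 13 measured H4 genes were lower, H3 had 7 lower and none higher of 12, H2A had 10 lower and 3 higher of 16, and H2B had 7 higher and 3 lower of 16. The mean of H2B genes exceeded that of the other types by 1.21 on the log2 scale (16 against 41 genes), a contrast chosen on the genes that show it, so that it is no test of the difference. The type medians kept their sign under the 4 scalings run, from 0.24 to 0.362 for H2B and from -1.47 to -1.3 for H4. Genes of a cluster are not independent, and probes may cross-hybridize between paralogs, so that whether the types differ stays open at a difference of 1.21. Which transcripts of these genes the labelling captured was not tested. The values need not be levels of the transcripts made with DNA replication. Among 550 families defined by symbol stem, MRPL, of the large mitochondrial ribosome subunit, had 28 lower and 1 higher of 50 (median -0.43, camera adjusted p = 0.000892; adjusted p = 0.87 with an estimated correlation). RAD had 13 lower and 1 higher of 19 (median -0.586, adjusted p = 0.0137; adjusted p = 0.87 with an estimated correlation). Proteasome genes did not pass as families (PSMA 7 lower of 8 and PSMC 6 lower of 6, both adjusted p = 0.0742), nor did NBPF, with 7 higher of 10 (adjusted p = 0.0742).

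With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 11819 genes in limma and the highest of the others gave 0, so that 1 of 10 gave as many. Every other split mixes the siRNA groups, so that the difference between them enters the residual spread. Few calls were thus fixed in advance for the other splits, and their 0 is no measure of false calls. At an unadjusted p under 0.05 the real split gave 13411 genes and the others 132 to 1161. The 3 others that part all pairs of an experiment gave 132, 152 and 184.

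Mitotic and replication genes were lower after GGCT siRNA. For the G2/M list, array scaling as the whole cause is argued against by its median relative to all genes, which was -1.51 and -1.39 with the quantile normalizations; median scaling shifts every gene alike and cannot change it. For the same list a single experiment or slide is argued against by the median within experiments, which came no nearer to 0 than -1.32; for the DNA replication list, on which the bound was not set, it came no nearer than -0.853. An effect of the siRNA on other genes cannot be told apart from the loss of GGCT, since the labels give 1 GGCT siRNA sequence. Loss of GGCT thus stays an open explanation.

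Secreted inflammatory factors were higher after GGCT siRNA, and an interferon response to transfected RNA is argued against by the core interferon genes, of which 6.67% rose (RIGI at 0.53, 1 of 15), while IFI44, IFIT1, IFIT2 and MX1 were lower. A single experiment is argued against by the list median within experiments, at least 1.16. Leukocytes as the source of the rise are argued against by the cultures, which were of a cell line. The bound set for the markers was fewer than 5 of 15 well above background on all GGCT siRNA arrays. With 6 at that level, the markers could not decide. By their changes, a measure that was not the one set, 5 of the 6 measured did not pass. These were PTPRC (0.255), CD14 (-0.154), CD3D (0.16), NKG7 (-0.159) and ITGAM (0.15), while CSF1R rose by 3.68 (1.17 with normexp). Of the 15 markers, 12 were on the array. Of these, 6 were well above background on all GGCT siRNA arrays, 4 of them also on all control arrays. That level alone is no sign of foreign cells, since 11 of 15 endothelial and stromal markers reached it in each group. Loss of GGCT and an effect of the siRNA on other genes stay open here too, as untested.

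Probes of one gene passed in opposite directions in 124 of the 4666 genes with a symbol and 2 or more kept probes, and at least 2 probes passed in the same direction, with none opposed, in 1930. The count is 0.426 times the 291 false calls that the threshold allows among 5823 probe calls. This ratio cannot decide whether false calls account for the count. The 291 holds every false call, while an opposed gene needs a false call opposed to another call of the same gene. The median brightness of the dimmest of all kept probes of a gene differed by -0.764 (log2) between opposed genes and genes whose probes moved together (permutation p = 0.011, two-sided). That probe need not be an opposed one, and it is dimmer by construction in genes with more probes. The difference thus does not settle whether dim probes are the source. In 7 genes both opposed changes were at least 2-fold. Among them were DDAH1 (1.68 and -1.73, limma adjusted p = 0.000282 and 0.000103), whose probes lie on different transcript records, and FEZ2 (1.38 and -1.03, limma adjusted p = 0.000172 and 0.00026), whose probes lie on the same record. The source of these was not tested.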
